A study of Mus musculus with 15 samples.

How the data were processed

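RNA sequencing (RNA-seq) libraries were made from 15 mouse samples, 3 in each of 5 groups. The groups were healthy brain, untreated GL261 glioma, and GL261 glioma treated with the anti-VEGF-A antibody B20.4.1.1 at 50, 100 or 200 µg per dose. Per the labels' protocols, dosing began on day 10 after implantation and was repeated every 3 days, the mice were perfused before collection, and libraries were made from total RNA with a NEBNext Ultra kit.

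For each library the authors deposited a table of transcripts with their exon coordinates and abundance as FPKM (fragments per kilobase of transcript and M mapped fragments). Per the submitters' processing notes, reads were aligned with STAR to the mm10 mouse genome and transcripts were assembled and quantified with Cufflinks. Versions, parameters and the annotation used in assembly were not given in the sources used here. The deposited FPKM values came from a separate assembly of each library and carried no gene names, so a transcript in one library had no fixed counterpart in the next. A gene whose reads were too sparse to join was listed as several short pieces, and neighboring genes whose reads touched were listed as a single transcript. FPKM is relative to a library's total, so a rise in a few abundant transcripts lowers the others. Spliced transcripts lay on both strands at about equal rates relative to annotated genes, so strand was ignored and overlapping or antisense genes could not be told apart.

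Transcripts were assigned to genes of the GENCODE M21 annotation of mm10 (55536 genes, of which 20074 took up a transcript in some library). The value of a gene was the sum over every transcript on its exons of FPKM multiplied by the share of the gene's exonic length that the transcript covered. Single-exon transcripts shorter than 200 bp were set aside. This rule replaced earlier ones after their calls had been seen. It was chosen on the agreement of replicates and on stray zeros, over 13506 genes. Mean correlation between replicates was 0.862 for a plain sum of the FPKM of intron-matched transcripts, 0.897 for the same transcripts weighted by length, 0.905 with unspliced pieces added and 0.916 for the rule used. Genes at 0 in some tumor libraries but at 5 FPKM or more in another numbered 2064, 1477, 1125 and 839 under these rules. The plain FPKM sum is the value named in the design fixed before the data were examined, so its count of genes is given beside that of each comparison.

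A gene was treated as uncertain where its transcripts also covered another gene, where it overlapped another annotated gene, or where it had near-identical copies. An exact 0 can be a failed assembly, since genes used by every cell were also at 0 in single libraries, so such genes are described as listed at 0, with library values unless they are uncertain for another reason.

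Groups were taken from sample titles and source names. The agent tag disagreed with them for replicate 3 of all 4 tumor groups, 4 libraries in all, and regrouping by that tag and leaving out these libraries were both tried. The labels say only that the samples of a group are individual samples, so p-values measure the spread between these samples.

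Tests were made with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) on log2(FPKM + 1), with trend and robust options off. Fold changes are on that scale, which understates the change of low genes. Genes needed a mean of at least 1 FPKM over the libraries of the fit. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Tumor and healthy brain were compared over their 6 libraries. Comparisons of dose groups came from a single fit of the 12 tumor libraries, which shared one estimate of the spread. They were each dose against untreated tumor, the mean of the 3 dose groups against untreated tumor, and an F test for any difference among the 3 doses. For the F test the change from 50 to 200 µg is given. A linear trend, expressed per 100 µg, was fitted apart on the same libraries, with dose as a number and its own estimate of the spread. That makes 7 comparisons.

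There were 28 gene lists, and those with at least 5 tested genes were tested with camera in limma, two-sided, at a preset correlation between genes of 0.01 and adjusted over the lists of a comparison. The lists covered endothelial cells, tip cells, angiogenic ligands, pericytes, the blood-brain barrier, hypoxia, proliferation, extracellular matrix, glioma stem cells, neurons, oligodendrocytes and their precursors, astrocytes, microglia, monocytes and macrophages, T and NK cells, B cells, neutrophils, dendritic cells, MHC class II, immune checkpoints, interferon response, red blood cells, immediate early genes, choroid plexus, meningeal fibroblasts, skeletal muscle and mitochondrially encoded genes. Each list test was repeated with an estimated correlation.

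Named genes followed a rule. For tumor against healthy brain they were the 10 largest positive and the 10 largest negative log2 fold changes among called genes with at least 10 FPKM in the higher group and no overlap between groups. Predicted genes, RIKEN clones, small RNA, immune receptor segments and mitochondrial genes were left out of this pick. For doses the same rule held with at least 2 FPKM, all genes passing where there were fewer, and the 5 smallest p-values where none passed. With 3 libraries against 3, chance alone separates the groups without overlap for 10% of genes. The 10 genes of the VEGF axis and up to 4 members of each list by smallest p were always included, except 1 gene that is not reported here. Other names were chosen after their values were seen.

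The groups, tests, lists, naming rule and most alternatives were set before the data were examined. The alternatives were a pseudocount of 0.1, no filter or a mean of at least 5 FPKM, median-of-ratios and quantile scaling, a trended robust prior, all 15 libraries in a single fit, the replicate number as a block, regrouping by agent tag, and leaving out each library. Alternatives added after seeing the data were the other assignment rules, a batch term or exclusion for 4 libraries with few genes in pieces, exclusion of 2 libraries that stood apart, removal of a trend on gene length, only genes not joined to a neighbor (at most 20% of their value from transcripts shared with another gene), and the left-out libraries of groups outside a comparison. All 200 µg libraries are among the 4 with few genes in pieces. In comparisons of dose groups the batch term is therefore set by 100 µg replicate 3 against its partners. A call lost under it at 200 µg can reflect the wider error that this brings.

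Mapped depth was not among the deposited columns. It was estimated from the FPKM confidence limits, which Cufflinks sets by fragment counts, at 16.7 to 59.7 M fragments per library. This estimate entered no fit and was used only to describe the libraries and to weigh depth as an explanation.

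Each fit was tested on simulated data with 100 changed genes at each size. At a log2 change of 1, it recovered 19% for tumor against brain, 43% at 50 µg, 40% at 100 µg, 33% at 200 µg, 51% for all treated, 48% for the trend and 40% among doses. At a log2 change of 2 the shares were 61, 82, 85, 81, 92, 86 and 84%. Calls among unchanged genes numbered 8, 7, 13, 9, 11, 12 and 5. The simulated noise was independent between genes, with no batch and no library that stood apart. These counts therefore do not measure false calls in the real libraries. Changed genes were drawn from those well above the 1 FPKM needed for testing, so recovery of low genes was not measured. The adjusted threshold is stricter where fewer genes change. The real tumor and brain libraries gave 9245 calls, far more than the genes changed here. The shares of 19 and 61% can therefore understate recovery in that comparison. For the trend the size is the change at 200 µg.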

Results

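Gene expression was measured by RNA-seq in healthy mouse brain and in GL261 tumors, a mouse glioma line grown in the brains of C57BL/6 mice. Tumor-bearing mice were left untreated or received B20.4.1.1, an antibody that binds VEGF-A, the main growth factor for blood vessels, at 50, 100 or 200 µg per dose. Each of the 5 groups held 3 libraries. The antibody binds the protein, so no transcript served as a check of the dose labels, and the agent tag of 4 tumor libraries disagreed with the title that set their group. Estimated depth was 19.4, 16.7 and 59.7 M fragments in the healthy brain libraries and 19.3 to 35.7 M in the tumor libraries. Each library listed 38194 to 89641 assembled transcripts.

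The tumor libraries differed in ways that the dose did not fully explain. Genes listed in pieces made up 12.1, 11.4 and 10.5% of genes in untreated tumors, 11.1, 10.2 and 18.4% at 50 µg, 9.06, 11.02 and 3.63% at 100 µg, and 3.93, 4.43 and 4.04% at 200 µg. Replicate 3 at 100 µg thus lay with the 200 µg libraries, and the share separated these 4 libraries from the other 8. The first principal component, 24.9% of the variance, placed 100 µg replicate 3 at 39.6 and the 200 µg libraries at 38.1 to 46.7, while 7 of the others lay between -37.7 and -14.9. Replicate 3 at 50 µg stood apart from all others, at 13.01 on the first component and -83.6 on the second.

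**Figure D1:**
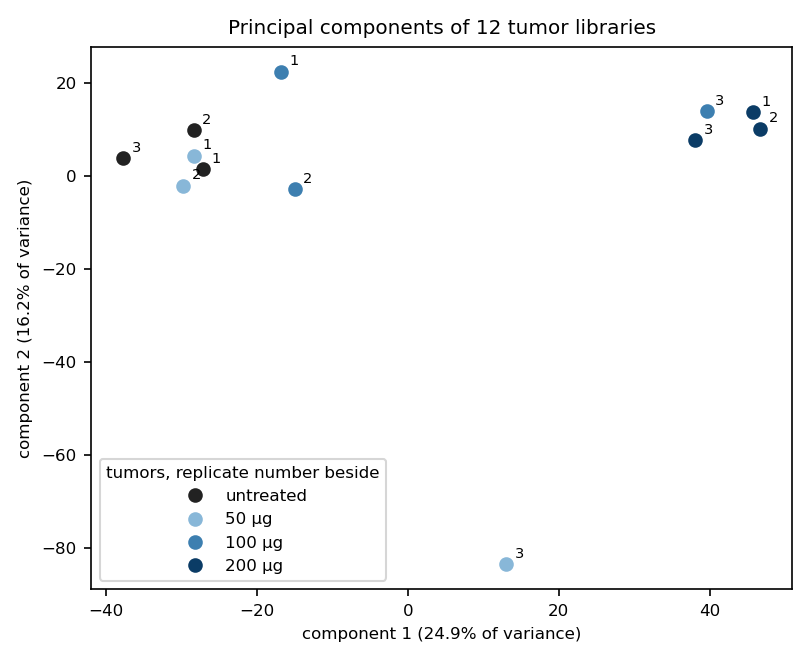
Principal components of the 12 tumor libraries on log2(FPKM + 1), the first on the horizontal axis (24.9% of variance) and the second on the vertical axis (16.2%), 1 point per library colored by dose group. The 3 libraries at 200 µg and replicate 3 at 100 µg lie on the right, and replicate 3 at 50 µg lies alone at the bottom.

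Untreated tumor was compared with healthy brain to ask how the glioma differs from its host tissue. Genes of dividing cells, of the extracellular matrix, of the interferon response and of antigen presentation were far higher in tumor, and genes of neurons, myelin and astrocytes were far lower. Vim, an intermediate filament of mesenchymal and glial cells, rose from 16.1 ± 2.60 FPKM in brain to 1358 ± 252 in tumor (SD, n = 3), a log2 fold change of 6.31 (SE 0.21, adjusted p = 8.05e-06 by limma). Snap25, a synaptic vesicle fusion protein, fell from 812 ± 281 to 3.71 ± 1.42 FPKM, a log2 fold change of -7.41 (SE 0.34, adjusted p = 1.4e-05). H2-Ab1, a chain of MHC class II, rose from 1.45 ± 0.400 to 352 ± 180 FPKM, and the non-coding RNA H19 from 2.10 ± 0.322 to 711 ± 505 FPKM.

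Of 14885 genes tested, 9245 were called, 5022 higher and 4223 lower in tumor. With the plain FPKM sum 6279 were called, of which 5749 were shared. The median of all genes was 0.16 on the log2 scale and -0.07 after median-of-ratios scaling, which gave 4186 higher and 4881 lower, and changes are to be read against that shift. Next to Vim, H19 (log2 fold change 7.48, SE 0.66) and H2-Ab1 (7.03, SE 0.43), the largest rises were in Krt8, a keratin (7.25, SE 0.24), H2-Aa (6.93), Gpnmb, a glycoprotein of macrophages (6.89), Cd74, the MHC class II invariant chain (6.58), Car6, a carbonic anhydrase (6.35), Apol9a (6.33), which has near-identical copies, and Timp1. Timp1, an inhibitor of metalloproteases, was listed at 0 in every brain library and at 97.9, 110 and 82.2 FPKM in untreated tumors. The largest falls were in Pcp4 (-7.52), Snap25, Stmn3 (-7.35), Camk2a, a kinase of excitatory synapses (-7.21, SE 0.22), Ddn (-7.09), Igsf5 (-7.09), Sult4a1 (-7.07), the neuropeptide Sst (-6.95), Hpca (-6.95) and the vesicular glutamate transporter Slc17a7 (-6.93). Pcp4 and Igsf5 overlap on the genome and cannot be told apart.

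All 23 proliferation genes rose, among them the mitotic cyclin Ccnb1 (5.37), Cdk1 (4.48) and Top2a (5.95), with an adjusted p for the list of 1.98e-09 by camera in limma. All 18 interferon response genes rose, including Irf7 (4.27), Bst2 (5.63) and Gbp2 (5.49), with a list p of 3.01e-08. Of 16 matrix and mesenchymal genes 14 rose, among them Cd44 (4.77), with a list p of 1.47e-05. All 8 MHC class II genes rose, with a list p of 0.00109, and 12 of 15 monocyte and macrophage genes rose, such as Cd14 (2.83) and Arg1 (3.62), with a list p of 0.00152. Of 14 glioma stem cell genes 10 rose, including Nes (3.31) and Itga6 (3.19), and 3 fell, including Sox9 (-3.24), with a list p of 0.0393. All 16 neuron genes fell, among them Camk2a, Stmn2 (-6.08) and Syt1 (-5.60), with a list p of 7.7e-09. Of 11 astrocyte genes 10 fell, such as Slc1a2 (-5.78) and Gjb6 (-4.37), with a list p of 0.000134, and 9 of 12 oligodendrocyte genes fell, such as Mbp (-4.46) and Mag (-4.08), with a list p of 0.000249. These were 9 of 22 lists tested, and none held with correlations estimated from the data. Those adjusted p = 0.356 with an estimated correlation for proliferation, MHC class II and monocytes, 0.24 for matrix, interferon and neurons, 0.271 for oligodendrocytes and astrocytes, and 0.291 for glioma stem cells. Counts adjusted over the list alone were the same for these lists.

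Vessel genes moved both ways in tumor against brain. Endothelial genes showed 4 higher, such as Cd93 (2.12), and 3 lower, such as Tek (-1.70), of 20, with a list p of 0.744 and 2 each way adjusted over the list alone. Tip cell genes showed 6 higher, among them Hspg2 (4.58) and Esm1 (2.91), and 1 lower of 12 (list p of 0.125). Angiogenic ligands showed 4 higher and 3 lower of 13 (0.731), among them Cxcl12 (-3.15) and Tgfb1 (1.95), pericytes 3 higher and 4 lower of 13 (0.759), and the blood-brain barrier 3 higher and 5 lower of 13 (0.602), with the transporters Slco1c1 at -3.33 and Slc2a1 at 2.80. Of 21 hypoxia genes 11 rose, among them Hk2 (2.50) and Car9 (2.76), and 3 fell, among them Ndrg1 (-3.64), with 12 and 3 adjusted over the list alone (list p of 0.0586). Microglia genes split into 2 higher, Olfml3 (2.69) and Tmem119 (2.93), and 7 lower, such as Siglech (-2.40) and P2ry12 (-2.34), of 10 (list p of 0.0586). Oligodendrocyte precursors showed 6 higher and 3 lower of 10 (0.44), T and NK cells 6 higher of 8 (0.0793), checkpoints 2 higher of 6, Cd276 (2.66) and Cd274 (3.44) (0.34), and immediate early genes 6 higher and 1 lower of 10 (0.115). Choroid plexus showed 2 lower of 8, Foxj1 (-2.21) and Clic6 (-1.59), with 1 adjusted over the list alone (0.0586), and meningeal fibroblasts 2 higher and 3 lower of 6 (0.602). Too few genes were tested for the remaining lists. Among them the dendritic cell genes Irf8 (2.73) and Itgax (2.80) rose and Zbtb46 (-0.84) fell, Acta1 of skeletal muscle fell (-2.49), mt-Nd1 fell (-1.27) among all genes but not over its list alone, and Csf3r of neutrophils (-0.43) and the hemoglobin genes Hba-a1 (0.67) and Hbb-bs (0.38) did not pass. No B cell gene reached the level for testing.

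Within the VEGF axis, Vegfa rose from 17.6 ± 3.41 FPKM in brain to 54.0 ± 15.5 in tumor (log2 fold change 1.54, SE 0.26, adjusted p = 0.00257 by limma). Its relative Pgf, placental growth factor, rose by 1.89 (SE 0.32, adjusted p = 0.0023), and the lymphatic receptor Flt4 by 0.81 (SE 0.16, adjusted p = 0.00418, but 0.327 under the plain FPKM sum). The main endothelial receptors showed no call, at -0.01 for Flt1 (adjusted p = 0.946) and 0.39 for Kdr (adjusted p = 0.306). Removal of a trend on gene length gave Flt1 a call in the other direction (0.57, adjusted p = 0.0139). Nrp1 (-0.19), Nrp2 (0.63), Vegfb (-0.44) and Vegfd (-0.86) did not pass, and Vegfb and a neighbor were at times assembled as a single transcript. Vegfc was listed at 0 in all 12 tumor libraries and at 0, 1.91 and 1.27 FPKM in brain.

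The antibody was given at 3 doses to ask what VEGF-A blockade changes in the tumor. Across doses Vegfa stayed within its spread, at 59.9 ± 26.4, 62.0 ± 20.8 and 58.8 ± 5.04 FPKM at 50, 100 and 200 µg (SD, n = 3), with log2 fold changes of 0.07, 0.19 and 0.16 (adjusted p = 0.982, 0.938 and 0.821 by limma). Nrp2, a co-receptor of VEGF family ligands on chromosome 1 (mm10, 62703285 to 62818695), was at 5.35 ± 0.893 FPKM in untreated tumors, 5.92 ± 0.820 at 50 µg, 12.8 ± 2.73 at 100 µg and 12.1 ± 1.47 at 200 µg. It was called at 200 µg (1.04, SE 0.20, adjusted p = 0.0266) and in the trend (0.58 per 100 µg, SE 0.14, adjusted p = 0.0261), but not at 100 µg (1.11, adjusted p = 0.108). No other gene of the axis was called at any dose, and at 200 µg the values were -0.68 for Vegfb (adjusted p = 0.165), -0.65 for Flt4 (0.108), -0.53 for Pgf (0.335), -0.22 for Kdr (0.76), -0.08 for Flt1 (0.826) and 0.11 for Nrp1 (0.833). Vegfd was too low to test in tumors. The call of Nrp2 at 200 µg ended under the plain FPKM sum (adjusted p = 0.0734), under a batch term for the 4 libraries with few genes in pieces (0.67, adjusted p = 0.467) and without any 1 of the untreated libraries (0.0627, 0.0873 and 0.0815) or of the 200 µg libraries (0.109, 0.0701 and 0.0555, each in replicate order). Its trend ended under the plain FPKM sum (adjusted p = 0.111), under the batch term (0.471) and without untreated replicate 2 or 3 (0.0565 and 0.0566) or 200 µg replicate 1 (0.0824).

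**Figure D2:**
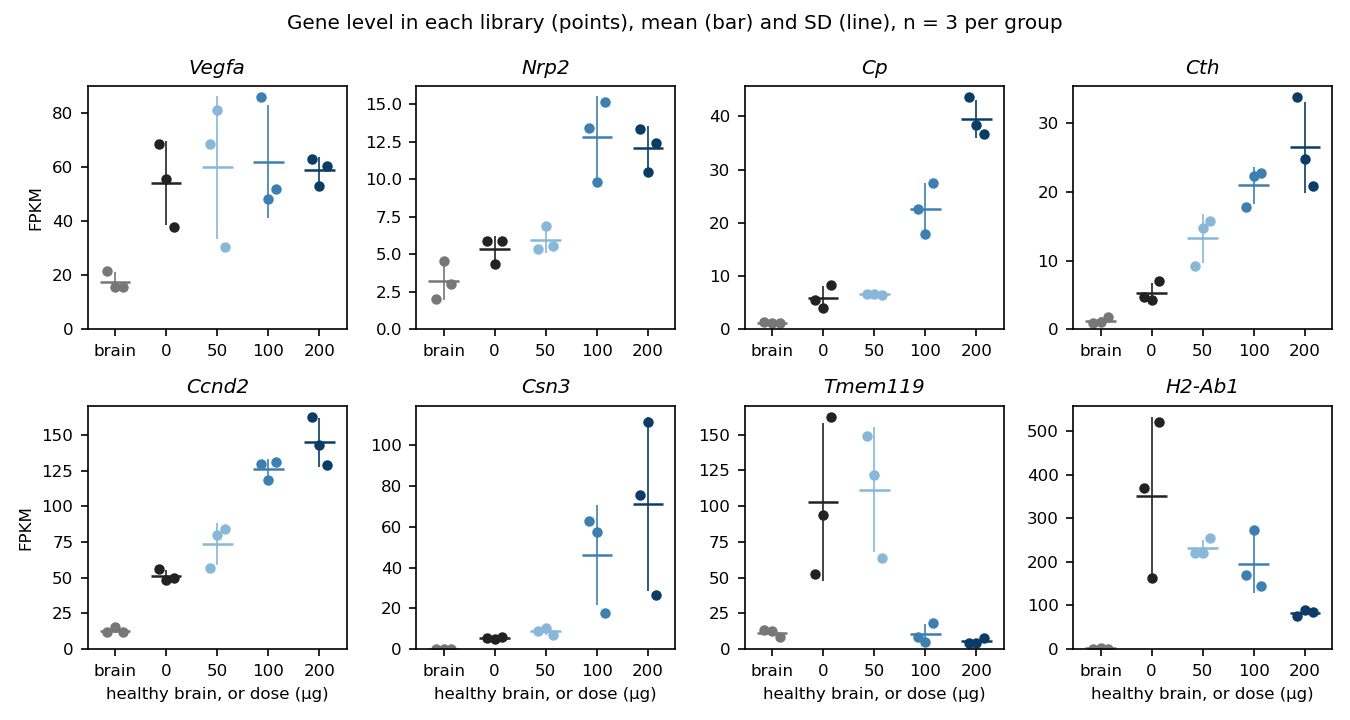
FPKM of Vegfa, Nrp2, Cp, Cth, Ccnd2, Csn3, Tmem119 and H2-Ab1 (vertical axes, from 0) in healthy brain and in tumors at 0, 50, 100 and 200 µg (horizontal axis), with 1 point per library, a bar at the mean and a line for the SD (n = 3). Vegfa lies near 54.0 to 62.0 FPKM in all tumor groups, while the mean of Cp goes from 5.87 FPKM in untreated tumors to 39.5 at 200 µg and that of Tmem119 from 103 to 5.39.

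At 50 µg no gene was called among 13407 tested with limma, and 531 had an unadjusted p under 0.05. Genes of tip cells, the sprouting front of new vessels, fell as a list. All 11 tested members had negative estimates, with a median of -0.43, among them Col4a2 (-0.98) and Plvap (-1.09), yet none passed alone, over all genes or adjusted over the list alone. The list p was 0.0329 by camera in limma, against an adjusted p = 0.875 with an estimated correlation. The list call ended under the plain FPKM sum (0.325), among only genes not joined to a neighbor (0.229) and under the batch term (0.0647). The 19 other lists tested had adjusted p from 0.15 to 0.884, and medians and tests differed in sign for the blood-brain barrier (-0.05, test up), proliferation (-0.06, test up) and microglia (0.02, test down).

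The 5 smallest p-values at 50 µg, none passing at an adjusted p of 0.445 by limma, were for Nmnat1 (1.82), Gm49437 (-2.55), Star (-2.15), Gm6142 and Rpl6l, which are uncertain because of transcripts joined to neighbors or near-identical copies. Gm6142 was listed at 0 in all untreated libraries and Rpl6l at 0 in all 50 µg libraries. In lists too small to test, Zbtb46 (0.51) and Ttr (-3.02) passed over their list alone. With the plain FPKM sum 3 genes were called. Counts without a single library were 4 (untreated replicate 1), 7 (50 µg replicate 1), 1 (50 µg replicate 2) and 1 (100 µg replicate 2).

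At 100 µg few genes were called, most of them higher. Cp, the copper-carrying ferroxidase ceruloplasmin (chromosome 3, 19957054 to 20009145), rose from 5.87 ± 2.20 to 22.7 ± 4.83 FPKM (log2 fold change 1.81, SE 0.23, adjusted p = 0.0348 by limma). Cth, which makes cysteine from cystathionine (chromosome 3, 157894248 to 157925077), rose from 5.32 ± 1.44 to 20.9 ± 2.70 FPKM (1.81, SE 0.26, adjusted p = 0.0395). Ccnd2, cyclin D2 (chromosome 6, 127125162 to 127152193), rose from 51.5 ± 4.21 to 127 ± 6.96 FPKM (1.28, SE 0.18, adjusted p = 0.0395), and Slc1a4, a neutral amino acid transporter (chromosome 11, 20302180 to 20332713), from 12.4 ± 0.659 to 27.5 ± 2.74 FPKM (1.09, SE 0.15, adjusted p = 0.0395). Rhd, a blood group antigen gene (chromosome 4, 134864536 to 134896172), fell from 6.21 ± 1.52 to 1.67 ± 0.453 FPKM (-1.43, SE 0.21, adjusted p = 0.0395).

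In all 11 genes were called at 100 µg, 9 higher and 2 lower, with 1228 at an unadjusted p under 0.05. Quantile scaling gave 5 higher and 0 lower by limma. Hectd2 (1.47) and its overlapping antisense gene Hectd2os (1.51) cannot be told apart, and Cfap43 (1.63) was joined to a neighbor. Ltc4s was listed at 0 in all untreated, 50 µg and 200 µg libraries and at 3.29, 8.94 and 2.89 FPKM at 100 µg. The plain FPKM sum called 7 genes, of which 1 was shared, the batch term 34, of which 10 were shared, and regrouping by agent tag called 2, of which 0 were shared. Counts were 4, 0 and 3 without an untreated library, 3, 0 and 34 without a 100 µg library, and 0 and 0 without 200 µg replicate 1 or 2, in replicate order. The 34 without 100 µg replicate 3 and the 34 under the batch term are the same check, since that term amounts to leaving this library out here. Cth had an adjusted p of 0.0653 to 0.181 without any 1 of the untreated libraries or without replicate 1 or 2 at 100 or 200 µg, at log2 fold changes of 1.70 to 1.99, and Ccnd2, Slc1a4 and Rhd lost their calls in the same 7 cases. The call of Cp was lost in 6 of these, the exception being untreated replicate 3.

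Lists of proliferation, oligodendrocyte, hypoxia, microglia and monocyte genes fell at 100 µg, while no member of any list was called over all genes. All 23 proliferation genes had negative estimates, with a median of -0.47, among them Plk1 (-0.99) and Cdc20 (-0.82) (list p of 3.43e-06, adjusted p = 0.64 with an estimated correlation). All 9 oligodendrocyte genes were negative, with a median of -0.81, and 4 of them fell when adjusted over the list alone, namely Opalin (-2.30), Mog (-1.49), Mal (-0.81) and Cldn11 (-1.26) (list p of 3.43e-06, adjusted p = 0.0953 with an estimated correlation). Of 21 hypoxia genes 18 were negative, such as Ldha (-0.59) and Eno1 (-0.82) (0.000127, adjusted p = 0.541 with an estimated correlation). The microglia list fell with 7 of 7 negative and 2 passing over the list alone, Tmem119 (-3.20, adjusted p = 0.0727 over all genes) and Olfml3 (-1.12) (0.0214, adjusted p = 0.541 with an estimated correlation). The monocyte and macrophage list fell with 13 of 17 negative and 1 passing over the list alone, Cd14 (-1.17) (0.0316, adjusted p = 0.698 with an estimated correlation).

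Both lists that rose at 100 µg were the blood-brain barrier, with 8 of 11 positive and 3 passing over the list alone, Slc7a5 (0.71), Abcg2 (0.69) and Slco1a4 (1.37) (0.038, adjusted p = 0.541 with an estimated correlation), and the interferon response, with 13 of 18 positive, such as Gbp2 (0.77) (0.0348, adjusted p = 0.773 with an estimated correlation). Under the batch term these rises had list p of 0.236 and 0.531, and under the plain FPKM sum 0.501 and 0.111. The falls of the microglia and monocyte lists ended under the plain FPKM sum (0.165 and 0.0731). The 13 other lists tested had p from 0.263 to 0.68 by camera in limma, with a median of 0.02 and a test down for immediate early genes. Among them Fgf1 (1.09) passed over its list alone, as did Zbtb46 (0.53) and Ttr (-3.13) in lists too small to test.

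At 200 µg more genes were called than at 100 µg. Under the batch term the counts were 37 and 34, with 1583 and 1800 at an unadjusted p under 0.05. That term rests on 100 µg replicate 3 against its partners and widens the error at 200 µg. The counts under it therefore do not show that the doses are alike. Cp rose further, to 39.5 ± 3.64 FPKM (log2 fold change 2.60, SE 0.23, adjusted p = 0.00141 by limma). Csn3, kappa-casein of milk (chromosome 5, 87925579 to 87932665), rose from 5.37 ± 0.562 to 71.1 ± 42.5 FPKM (3.28, SE 0.53, adjusted p = 0.0163). Tmem119, a membrane protein that marks microglia in healthy brain (chromosome 5, 113793729 to 113800516), fell from 103 ± 55.3 to 5.39 ± 1.98 FPKM (-3.92, SE 0.51, adjusted p = 0.00784). Its ratio to the microglial gene P2ry12 was 28.3, 51.2 and 110 in untreated tumors against 1.10, 1.05 and 0.602 in brain, in replicate order. Vgf, a neurosecretory protein (chromosome 5, 137026392 to 137033351), fell from 185 ± 91.6 to 15.4 ± 0.519 FPKM (-3.34, SE 0.55, adjusted p = 0.0171). H2-Ab1 (chromosome 17, 34257689 to 34269419) fell from 352 ± 180 to 83.2 ± 6.00 FPKM (-1.91, adjusted p = 0.0266).

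In all 437 genes were called at 200 µg, 308 higher and 129 lower, with 3191 at an unadjusted p under 0.05. Genes called higher had a median exonic length of 3598 bp and those called lower 1629 bp, against 2989 bp for all genes tested. Of the 437, 90 drew on transcripts shared with a neighbor. The naming rule also took Lbhd2, listed at 0, 2.16 and 0 FPKM in untreated tumors and at 17.4, 26.2 and 5.33 at 200 µg, Glod5, at 9.53, 17.6 and 19.99 against 0, 0 and 3.63, and Jsrp1, at 5.26, 14.9 and 11.8 against 0, 0 and 1.17. Several others were listed at 0 in a whole group. Zxdb was at 0 in all untreated libraries and at 7.44, 7.52 and 6.60 FPKM at 200 µg, but at 0, 0 and 6.11 at 100 µg and 0, 0 and 2.63 at 50 µg (0.20 under the batch term, adjusted p = 0.947), and Dcpp1, which has near-identical copies, at 0 and at 15.3, 9.60 and 2.06. Xpnpep1 was at 11.1, 12.4 and 13.9 in untreated tumors and at 0.0151, 0.0328 and 0 at 200 µg, but at 12.8, 14.1 and 0 at 100 µg, so it followed the 4 libraries with few genes in pieces, and its change was 0.13 under the batch term (adjusted p = 0.947). Ttr, a carrier protein of the choroid plexus, was at 49.6, 44.2 and 3.54 in untreated tumors and at 0 in all 200 µg libraries. Ell3, Rabepk (3.69, but -0.052 with groups by agent tag), Usp44 (3.41), Gzmm (3.02), Mt2 (-5.44), Tmem126a (-4.40), Ndufa1 (-3.57) and Mrps28 (-2.65) are uncertain because their transcripts also covered another gene, and Pgk1-ps1 (2.80) because it is a copy of Pgk1. Mt2 and Ndufa1 also followed the 4 libraries with few genes in pieces. At 100 µg Mt2 was at 405, 435 and 11.2 FPKM and Ndufa1 at 73.5, 146 and 8.52, and under the batch term they changed by -0.33 (adjusted p = 0.902) and -0.11 (adjusted p = 0.969).

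The batch term called 37 genes at 200 µg, of which 10 were shared with the 437, the plain FPKM sum 57, of which 40 were shared, intron-matched assignment 238, of which 214 were shared, and regrouping by agent tag 7, of which 0 were shared. Counts were 73, 73 and 50 without an untreated library, 1012 without 50 µg replicate 3, 1189 without 100 µg replicate 3, and 32, 43 and 286 without a 200 µg library, in replicate order. Of the genes above, Tmem119 lost its call only under the agent tag grouping (-2.12, adjusted p = 0.419), which ended those of all 30 results named at 200 µg, and Cp there (1.80, adjusted p = 0.359) and under the batch term (2.17, adjusted p = 0.0786). The call of Vgf ended under the batch term (-1.88, adjusted p = 0.449), without untreated replicate 2 or 3 (0.0621 and 0.074) and without 200 µg replicate 1 or 2 (0.0749 and 0.0601). Csn3 lost its call without any untreated library (0.0522, 0.0608 and 0.0624) and without 200 µg replicate 1 or 2 (0.076 and 0.0601). H2-Ab1 lost its call under the batch term (-1.33, adjusted p = 0.482), under the plain FPKM sum (0.0709), without untreated replicate 1 or 3 (0.0838 and 0.0946) and without each 200 µg library (0.106, 0.0872 and 0.0547).

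Vessel, myelin, neuron, microglia, antigen presentation and proliferation genes fell as lists at 200 µg, and none of the lists rose. Of 9 oligodendrocyte genes 2 fell over all genes, Cldn11 (-2.09) and Mag (-1.02), and 5 over the list alone (list p of 0.00633 by camera in limma, adjusted p = 0.516 with an estimated correlation). Tip cells had 9 of 11 negative, such as Pdgfb (-0.81) and Col4a2 (-0.80), and endothelial cells 15 of 18, such as Tie1 (-0.80) and Egfl7 (-0.78), with no member passing (0.0311 each, adjusted p = 0.72 and 0.927 with an estimated correlation). MHC class II had 8 of 8 negative, with H2-Ab1 passing over all genes and over the list alone (0.0311, adjusted p = 0.72 with an estimated correlation). Proliferation had 17 of 23 negative, such as Tyms (-0.90) and Mcm2 (-0.86), none passing (0.0311, adjusted p = 0.927 with an estimated correlation). Of 8 neuron genes Tubb3 fell (-1.69), with 4 over the list alone (0.0481, adjusted p = 0.72 with an estimated correlation), and of 7 microglia genes Tmem119 fell, with 2 over the list alone (0.0481, adjusted p = 0.72 with an estimated correlation). Without replicate 3 of 50 µg and of 100 µg, which stood apart, the list p was 0.0264 for oligodendrocytes and 0.0946 for the other 6. Under the batch term the calls of MHC class II (0.221), neurons (0.741), endothelial (0.056) and tip cells (0.0601) ended.

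Among the 13 lists tested without a call at 200 µg, single members rose. These were Fgf1, a fibroblast growth factor (1.44, list p of 0.748), the blood-brain barrier transporters Abcg2 (0.96) and Slco1a4 (1.82), with 4 over the list alone (0.203), and the astrocyte glutamate transporter Slc1a3 (1.03, list p of 0.89). The other list p were 0.169 for hypoxia and for glioma stem cells, 0.366 for oligodendrocyte precursors, 0.466 for monocytes, 0.89 for pericytes and matrix, 0.926 for checkpoints, 0.748 for immediate early genes and 0.942 for T and NK cells (median -0.02, test up) and interferon (median 0.08, test down). In lists too small to test, Zbtb46 rose (0.74) while Pax5 (0.09), S100a8 (0.92), Hba-a1 (-0.92), Col1a1 (-1.17), Mylpf (-1.44) and mt-Cytb (-1.37) did not pass over all genes.

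**Figure D3:**
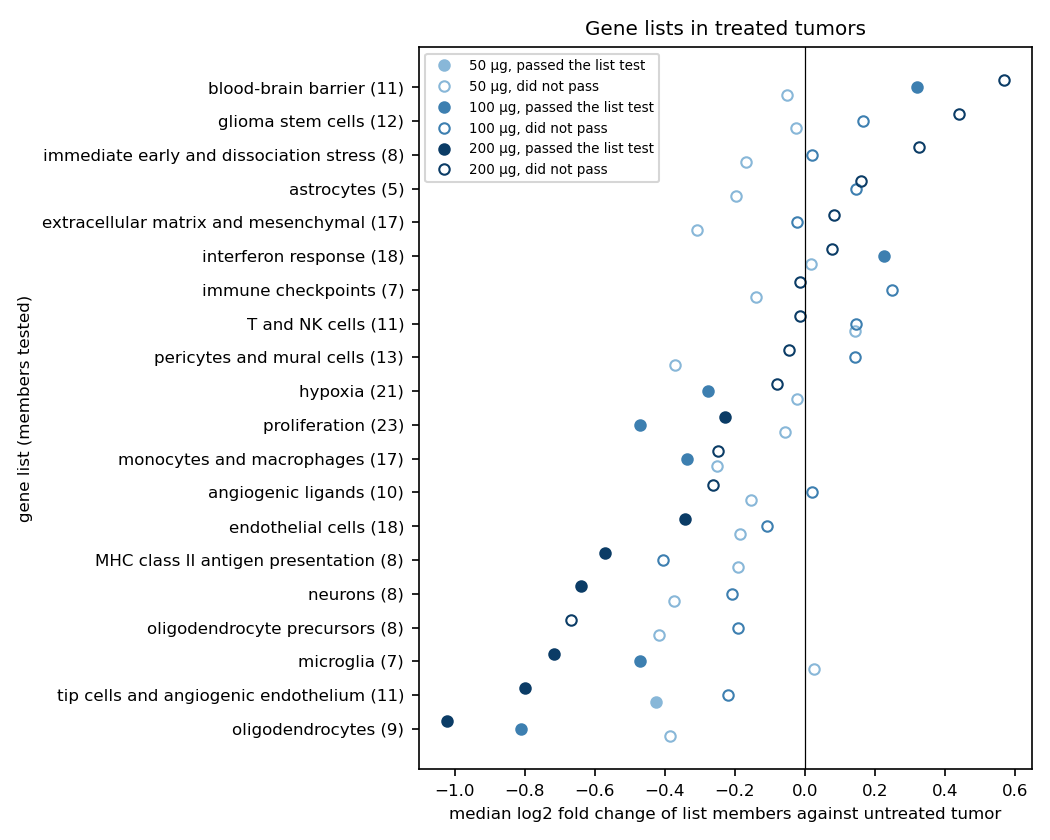
Median log2 fold change against untreated tumor (horizontal axis) of the tested members of 20 gene lists (vertical axis) at 50, 100 and 200 µg, filled where the list passed its test in limma. Filled points number 1 at 50 µg and 7 each at 100 and 200 µg, and at 200 µg all of them lie below 0.

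Over all doses together, Cth, Ccnd2 and Slc1a4 were among the genes higher than in untreated tumors. The mean of the 3 dose groups rose by 1.70 for Cth (SE 0.21, adjusted p = 0.0201 by limma), by 1.08 for Ccnd2 (SE 0.15, adjusted p = 0.0361) and by 0.84 for Slc1a4 (SE 0.12, adjusted p = 0.0373). Hectd2 (1.17) and Hectd2os (1.31) rose as an overlapping pair. In all 9 genes were called, 7 higher and 2 lower, with 1673 at an unadjusted p under 0.05. Oligodendrocyte genes fell as a list with 6 of 9 passing over the list alone, such as Cldn11 (-1.35) and Opalin (-1.61) (list p of 0.000253, adjusted p = 0.214 with an estimated correlation). Proliferation (21 of 23 negative, 0.0107), tip cells (9 of 11, 0.0295) and hypoxia (17 of 21, 0.0479) also fell without a member passing, each at an adjusted p = 0.748 with an estimated correlation. These calls ended under the plain FPKM sum (0.103, 0.0759 and 0.0759), and the other 16 lists tested had p from 0.0517 to 0.996.

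The plain FPKM sum called 15 genes for all treated tumors, of which 3 were shared, and the batch term 18, of which 2 were shared. Counts by limma were 1 without untreated replicate 2, 1, 3 and 19 without a 200 µg library in replicate order, 16 and 15 without 50 µg replicate 1 or 3, and 24 without 100 µg replicate 3. The call of Cth ended without untreated replicate 1 or 2 (adjusted p = 0.0818 and 0.116), without 200 µg replicate 1 or 2 (0.0574 and 0.0553) and under the batch term (0.0762). All 5 named results lost their calls in these 4 leave-outs and under the agent tag grouping. Ccnd2 and Slc1a4 lost theirs also without untreated replicate 3 (0.17 and 0.204), 50 µg replicate 2 (0.0692 and 0.0731) or 100 µg replicate 1 (0.0624 and 0.0694), without the 4 libraries whose agent tag disagrees (0.101 and 0.0986), under the batch term (0.0878 each) and under the plain FPKM sum (0.104 and 0.361), and Ccnd2 without 100 µg replicate 2 (0.0615).

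The linear trend asked which transcripts had a slope over dose, which does not require a steady change. Csn3 rose by 1.74 per 100 µg (SE 0.30, adjusted p = 0.00871 by limma), and Tmem119 fell by 2.23 per 100 µg (SE 0.38, adjusted p = 0.00871). The fall of Tmem119 was a step, with 149, 122 and 63.6 FPKM at 50 µg and 8.26, 4.99 and 18.4 at 100 µg, in replicate order. Single myelin genes were called lower, at -1.03 for Cldn11, -0.49 for Mag and -0.72 for Cnp. So were the replication and mitosis genes Mcm2 (-0.46), Tyms (-0.49) and Aurka (-0.59). Most members of the oligodendrocyte and proliferation lists were not called, and neither list held with an estimated correlation. The growth factor Fgf1 (0.80) and the transporters Abcg2 (0.51), Slco1a4 (0.95) and Slc1a3 (0.54) rose. H2-Ab1 fell by 0.95 per 100 µg (adjusted p = 0.00891).

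The trend was called for 1155 genes, 777 higher and 378 lower, with 3654 at an unadjusted p under 0.05. After median-of-ratios scaling 611 were higher and 458 lower. The plain FPKM sum called 262, of which 215 were shared, and the batch term called 0 by limma, with 1737 at an unadjusted p under 0.05. Under that term the slopes were 2.58 for Csn3 (adjusted p = 0.169) and -2.70 for Tmem119 (adjusted p = 0.227). Counts were 695 and 454 without untreated replicate 1 or 3, 684, 726 and 1924 without a 50 µg library, and 176, 255 and 767 without a 200 µg library, in replicate order. Intron-matched assignment called 670, of which 628 were shared.

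Other genes taken by the rule for the trend were Lbhd2 (1.69) and Hspb11, Car3, Zxdb, Dcpp1, Ell3 and Mfap1b, all listed at 0 in the untreated libraries. Hspb11 was at 0, 21.4 and 27.9 FPKM at 50 µg, 27.3, 29.4 and 0 at 100 µg and 32.3, 29.8 and 43.5 at 200 µg. Car3 was at 0, 0 and 10.5 at 50 µg, 0, 0 and 11.003 at 100 µg and 17.6, 17.3 and 10.2 at 200 µg, and Zxdb and Dcpp1 were as above. Ell3, Gzmm (1.67), Usp44 (1.64), Mt2 (-2.80), Tmem126a (-2.22), Tomm40 (-1.82) and Snhg3 shared transcripts or exons with another gene, Mfap1b, Rps10-ps2 and Rpl37 have near-identical copies, and Fcor, Xpnpep1 (0.052 under the batch term) and Ttr reached 0 in 200 µg libraries. Fcor was at 13.95, 26.9 and 13.1 FPKM in untreated tumors and at 0 in all 200 µg libraries. Snhg3 and Rps10-ps2 were at 0 in all 200 µg libraries and in replicate 3 at 50 and 100 µg. The lists that fell with dose were oligodendrocytes (3 of 9 called, 5 over the list alone, list p of 0.00559), proliferation (3 of 23 called, 3 over the list alone, 0.0169) and MHC class II (H2-Ab1 alone of 8, 0.037). They had an adjusted p = 0.765, 0.859 and 0.765 with an estimated correlation, and the last ended after median-of-ratios scaling (0.0533). Outside these lists, Tubb3 (-0.81), the glycolytic enzyme Pfkl (-0.57), Gpr17 (-0.93) and mt-Cytb (-0.72, but 0.098 under the batch term, adjusted p = 0.879) fell, and Spp1 (0.52), Zeb1 (0.39), Pdgfra (0.42), Lhfpl3 (0.68), Cd3g (0.47) and Zbtb46 (0.32) rose.

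The doses were also compared with each other. Between 50 and 200 µg, Cp rose by 2.42 (SE 0.23, adjusted p = 0.00723 for the F test over all 3 doses by limma), Lbp, a binding protein for bacterial lipopolysaccharide (chromosome 2, 158306493 to 158332852), by 1.95 (SE 0.27, adjusted p = 0.0324), Dmrta1 by 1.89 (SE 0.25, adjusted p = 0.0351) and the macrophage protease Mmp12 by 1.86 (SE 0.28, adjusted p = 0.0458). Tmem119 changed by -4.09 (SE 0.51, adjusted p = 0.0201), from 111 ± 43.7 to 5.39 ± 1.98 FPKM, the mitochondrial ribosomal gene Mrpl52 by -2.97 (SE 0.40, adjusted p = 0.0351) and Rhd by -1.22 (SE 0.21, adjusted p = 0.0383). Rabepk (3.52), Gzmm (3.39), Cfap43 (2.35), Star (2.34), Dennd2d (1.71), Mrps28 (-2.96) and Sod1 (-2.58) shared transcripts with a neighbor, and Pgk1-ps1 (3.26) is a copy of Pgk1. Of list members only Tmem119 was called, and no list test was made for this comparison.

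In all 34 genes differed among doses, of which 27 were higher and 6 lower at 200 than at 50 µg and 1 had no sign, with 2153 at an unadjusted p under 0.05. The median of all genes was 0.10 from 50 to 200 µg, and -0.01 after median-of-ratios scaling, which gave 11 higher and 5 lower of 17 by limma. Quantile scaling gave 17 higher and 7 lower. With the plain FPKM sum 14 were called, of which 6 were shared. Leaving out any 1 of the 12 libraries moved the count, to 17, 9 and 13 for the untreated, 17, 13 and 17 for the 50 µg, 17, 20 and 859 for the 100 µg and 7, 11 and 54 for the 200 µg libraries, in replicate order. Cp kept its call in each case but not under the plain FPKM sum (adjusted p = 0.106), the batch term (0.0903) or the agent tag grouping (0.142), and Tmem119 lost its call without untreated replicate 2 (0.0501), 50 µg replicate 1 or 2 (0.0855 and 0.0937) and 200 µg replicate 1 or 2 (0.0887 and 0.0705), and under the agent tag grouping (0.0778). Of the 15 named results the batch term kept 2 and the agent tag grouping 0, the plain FPKM sum 3 of 14, and leaving out a library 4 to 15. Lbp, Dmrta1, Mmp12, Mrpl52 and Rhd lost their calls under these 3 settings, and without untreated replicate 1 or 2, 50 µg replicate 1, 100 µg replicate 1 or 2 or 200 µg replicate 2, at an adjusted p of 0.052 to 0.178.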

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

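The counts of genes under other splits of the samples were planned before the data were examined, and the tests of gene length, library making, cell type and wrong labels were chosen after the results were seen. Other splits of the same libraries were fitted for each comparison, 10 for those of 3 against 3 and 100 drawn for the others. For tumor against brain 1 of 10 splits called as many genes as the real one (9245, highest other 0), at 50 µg 10 of 10 (0, highest other 7), at 100 µg 1 of 10 (11, highest other 4) and at 200 µg 1 of 10 (437, highest other 2), and 10 splits are too few for a share under 0.05. At 50 µg the share was also fixed in advance, since no split can call fewer than 0 genes. Counting the real split, as many genes were called in 1 of 100 for the trend (1155 genes against 3 in the highest other). The share was 1 of 100 for the difference among doses (34 against 16) and 2 of 100 for all treated tumors (9 genes). These shares are under 0.05, which argued against a random grouping. They cannot tell dose from the 4 libraries with few genes in pieces, which include all those at 200 µg. For all treated tumors the highest other split called 216 genes. It set the 3 libraries at 200 µg against the rest, which points to a structure of the samples.

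Genes whose change differed between doses were singled out by the test of the difference itself. From 50 to 200 µg the log2 differences were 2.42 for Cp, 1.95 for Lbp, 1.89 for Dmrta1, 1.86 for Mmp12, -4.09 for Tmem119, -2.97 for Mrpl52 and -1.22 for Rhd. Those of Rabepk (3.52), Gzmm (3.39), Cfap43 (2.35), Star (2.34), Dennd2d (1.71), Mrps28 (-2.96) and Sod1 (-2.58) rested in part on transcripts joined to a neighbor, and that of Pgk1-ps1 (3.26) on a pseudogene.

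Single-exon transcripts inside introns, which no comparison used, covered more sequence in 6 of the 9 treated tumors than in any untreated one. They covered 4248.4, 4564.2 and 5435.2 kb in untreated replicates 1 to 3, 6299, 7292.3 and 28456 kb in 50 µg replicates 1 to 3, 7519.9 and 14164 kb in 100 µg replicates 1 and 2, and 5657.7 kb in 200 µg replicate 2. In 200 µg replicate 1 they covered 5397.8 kb, within the untreated range, and in 100 µg replicate 3 and 200 µg replicate 3 they covered 3391.4 and 4117.2 kb, below it.

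The 437 calls at 200 µg are the pattern with the widest reach, and all libraries at that dose belong to the 4 with few genes in pieces, and gene length as the whole cause was argued against, since 469 genes were called with the length trend removed, 370 of them among the 437. A difference in library making may contribute, since the healthy brain library with the fewest genes in pieces differed from its partners in the same directions, by a median of -0.64 over 115 genes called lower (random sets -0.32 to -0.05) and 0.19 over 254 called higher (random sets -0.13 to 0.02). Outside those 4 libraries, 100 µg differed from 50 µg by a signed median of 0.42 over the 437 genes, with 88.1% moving the same way, against 0.08 in the higher of the other 2 splits, which are too few to decide whether library making acts alone. With a batch term the median signed change went from 1.23 (median SE 0.239) to 0.99 (median SE 0.388) and 10 of the 437 stayed called. As that term rests on 100 µg replicate 3 against its partners, lost calls can come from the wider SE. That brain library was also the deepest, with 59.7 M fragments against 19.4 and 16.7 M, so depth may stand behind its values, and dose, depth and library making cannot be told apart.

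Tmem119 fell at 200 µg, with 4.03, 4.47 and 7.66 FPKM against 52.8, 94.0 and 162 in untreated tumors, and fewer microglia, library making and a wrong label were weighed. A loss of microglia as the whole cause was argued against, since the other 6 microglia genes had a median change of -0.48 (-0.94 to 0.21) against -3.92 for Tmem119. Library making was argued against as well, since the 100 µg libraries outside the 4 with few genes in pieces stood at 8.26 and 4.99 FPKM, below the lowest untreated library at 52.8. Its ratio to P2ry12 was 28.3 to 110 in untreated tumors and 0.602 to 1.10 in brain, so much of it may come from cells other than microglia, and which cells lost it was not tested. The agent tag grouping gave -2.12 (adjusted p = 0.419 by limma), but a wrong label of replicate 3 as the cause was argued against, since without the 4 libraries whose tag disagrees the change was -3.77 and was still called by limma.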

How the results depend on the processing

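The batch, gene length, assignment, joined-gene and 2-library alternatives, and leaving out libraries outside a comparison, were added after seeing the data, and the others were planned. The plain FPKM sum was the gene value planned at the start. The rule that assigns transcripts to genes was itself chosen after its alternatives had been run, on replicate agreement and stray zeros. Tumor against brain kept its count within 1.5 times under every alternative fitted, from 6279 genes with the plain FPKM sum to 9848 with no filter. Named results kept their calls unevenly. Of 105 called for tumor against brain, the plain FPKM sum kept 92 of the 104 it could test. Of 30 called at 200 µg, median-of-ratios scaling kept 29, the plain FPKM sum 10, the batch term 3 and the agent tag grouping 0. Of 42 called for the trend, the same settings kept 38, 13, 0 and 0. Over gene lists, 1056 values stayed on their side of the threshold, 35 passed and 79 dropped out. Over single genes the numbers were 11881, 129 and 492, with 6 turning direction, and when leaving out a library 8042, 59 and 513. The cause was not tested unless named.

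Counts of called genes moved by over 1.5 times as follows. At 50 µg (0 by limma, 531 at an unadjusted p under 0.05) the count was 1 with a pseudocount of 0.1, 1 with no filter, 1 with groups by agent tag, 1 without the 4 samples whose agent tag disagrees, 3 with the plain FPKM sum, 2 with intron-matched assignment, 1 with intron-matched plus unspliced pieces, and 1 in only the 8 libraries outside the batch. At 100 µg (11) it was 4 at a mean FPKM of at least 5, 5 with quantile normalization, 3 with a trend and robust prior, 2 by agent tag, 59 without the 4 samples whose tag disagrees, 7 with the plain FPKM sum, 7 with the length trend removed, 34 with the batch term and 50 without the 2 libraries that stand apart. At 200 µg (437) it was 7 by agent tag, 909 without those 4 samples, 57 with the plain FPKM sum, 238 with intron-matched assignment, 37 with the batch term and 2304 without the 2 libraries that stand apart, of which 435 were shared. For all treated tumors (9) it was 5 at a mean FPKM of at least 5, 2 by agent tag, 40 without those 4 samples, 15 with the plain FPKM sum, 18 with the batch term and 42 without the 2 libraries. For the trend (1155) it was 3 by agent tag, 716 without those 4 samples, 262 with the plain FPKM sum, 670 with intron-matched assignment, 0 with the batch term (1737 at an unadjusted p under 0.05) and 2101 without the 2 libraries. For the difference among doses (34) it was 20 at a mean FPKM of at least 5, 17 with median-of-ratios scaling, 76 with all 15 samples in one fit, 562 without those 4 samples, 14 with the plain FPKM sum, 20 with intron-matched plus unspliced pieces and 1668 without the 2 libraries. Stricter filters test fewer genes and the exclusions use fewer samples.

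Leaving out 1 library gave 8297 to 9255 genes for tumor against brain, 0 to 7 at 50 µg, 0 to 34 at 100 µg, 32 to 1189 at 200 µg, 1 to 24 for all treated, 176 to 1924 for the trend and 7 to 859 among doses.

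Among named genes, directions that turned were those of Rabepk at 200 µg with groups by agent tag (-0.052), Xpnpep1 with the batch term at 200 µg (0.13) and in the trend (0.052), mt-Cytb in the trend with the batch term (0.10), Flt1 in tumor against brain with the length trend removed (0.57) and Vwf there with the plain FPKM sum (-0.24).

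With the replicate number as a block the counts were 8589 for tumor against brain, 0 at 50 µg (580 at an unadjusted p under 0.05), 0 at 100 µg (1237), 283 at 200 µg, 2 for all treated, 922 for the trend and 5 among doses by limma. No label says that the numbers pair samples. The deviations of same-numbered tumor libraries had a mean correlation of 0.0136 over 18 pairs (-0.0832 to 0.131), against -0.00648 over 36 pairs with different numbers (-0.219 to 0.208). These values showed no sign of pairing but cannot rule out a weak shared effect.

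Depth limits genes of low abundance, since assembly lists a gene in pieces or at 0 where reads are sparse. The share of genes in pieces ran from 3.63 to 27.8%, with 7.70% in the deepest brain library and 27.8 and 17.9% in the others. Estimated depth was 19.3 to 20.4 M fragments in untreated tumors and 25.6 to 35.7 M at 200 µg, so depth and dose go together. The share was 3.63% in 100 µg replicate 3 at 24.0 M, against 9.06 and 11.02% in its partners at 24.6 and 25.4 M, so depth alone did not set it.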

Other observations

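The gene lists below were drawn up after the calls had been seen, 4 in all, and all tests here were chosen after the result they bear on. A list of ATF4 targets and amino acid supply genes was higher at 100 and 200 µg. ATF4 is the transcription factor of the amino acid and stress response. The list also holds Atf4 itself, and ATF4 activity was not measured. Of 39 tested, 10 rose at 200 µg over all genes and 23 when adjusted over the list alone, among them Cth (2.12), Nupr1 (2.03), the cystine transporter Slc7a11 (1.79), Atf5 (1.55), Slc1a4 (1.25) and asparagine synthetase Asns (0.94). Median log2 changes were 0.26, 0.58 and 0.63 at 50, 100 and 200 µg. Adjusted over the 4 lists, camera in limma gave an adjusted p = 0.0576, 0.00717 and 0.0354 with an estimated correlation, and 0.0504 for the trend. Without the 2 libraries that stand apart these were 0.0571, 0.0695, 0.102 and 0.086, and among genes not joined to a neighbor 0.0505, 0.00921, 0.0554 and 0.049. The plain FPKM sum gave 0.0799, 0.00424, 0.0113 and 0.0328. Cth and Slc1a4 prompted the list, so it is not independent of them, and Slc7a5, Ddit4 and Atf3 are also in the lists set earlier.

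Of 17 genes tested at 200 µg from a list for the acute phase, the response of plasma proteins to inflammation, 11 had positive and 6 negative estimates. The list mixes plasma proteins with receptors and signaling genes such as Osmr and Stat3, and its members need not all rise in that response. Hp (2.35), Cp (2.60), Lbp (1.98), Trf (1.92) and Osmr (1.06) rose over all genes, and Mt2 fell (-5.44, uncertain because of shared exons, and -0.33 with the batch term). Among the negative estimates were C3 (-0.95), Saa3 (-0.66), Serpina3n (-0.17) and Lcn2 (-0.10), none passing. The list had an adjusted p of 0.0155 by camera in limma, but an adjusted p = 0.0684 with an estimated correlation and 0.0682 with the batch term, so it was not called in either. With the plain FPKM sum and an estimated correlation it was called, at an adjusted p = 0.0378, and 0.0486 at 100 µg.

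For the higher values of the list of ATF4 targets and amino acid supply genes, library making, a wrong label and chance were weighed. Library making as the whole cause at 100 µg was argued against, since the libraries outside the batch of few genes in pieces had list means of 5.77 and 5.79 (log2) against 5.08 to 5.21 in untreated tumors, although in those 8 libraries the list, with a median of 0.66, had an adjusted p = 0.097 by limma with an estimated correlation. At 200 µg library making stays open, as all libraries are in the batch, and the brain library with the fewest genes in pieces had a median of -0.14 on the list, inside the random range (-0.31 to 0.09). Within 100 µg, replicate 3, which is in the batch, had a list mean of 5.84, near its partners. Under the batch term the direction of the list at 200 µg stayed up. Both of these rest on that library alone, so they cannot settle it. A wrong label of replicate 3 was argued against, since libraries whose agent tag matches the title had means of 5.14 and 5.08 untreated, 5.79 and 5.77 at 100 µg and 5.96 and 5.82 at 200 µg, although grouping by the tag gave an adjusted p = 0.992 at 100 µg and 0.261 at 200 µg. Chance stays open beside an amino acid response to VEGF-A blockade as a candidate explanation, because the exact permutation of treated against untreated libraries, two-sided, gave p = 0.00455, the smallest that 220 splits can give, on genes chosen after calls in the same libraries.

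Ribosomal protein genes, 75 tested, had a median of -0.65 at 200 µg and an adjusted p = 0.0684 with an estimated correlation, and 73 genes of oxidative phosphorylation a median of -0.31 with 0.0781. Under the batch term the direction of the latter list turned at 200 µg, to up (adjusted p = 0.52 by camera in limma), as it did at 100 µg, for all treated tumors and in the trend (0.839, 0.694 and 0.654). The brain library with the fewest genes in pieces differed from its partners by medians of -0.62 (random sets -0.44 to -0.07) and -0.67 (random sets -0.46 to -0.02) on the same lists. Library making, or the greater depth of that library, could therefore account for these values without any effect of dose.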
